A study of Homo sapiens with 4 samples.

How the data were processed

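The study held 4 human samples, 1 per group: RNAPII ChIA-PET in CM at day 35 of differentiation, RNAPII ChIA-PET in iPSC at passage 45, H3K27ac ChIP-seq in CM, and a CM input. Groups were taken from the sample titles. The study concerned the titin gene TTN and its regulatory elements in cardiomyocytes. The input sample was not analysed here.

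Per the labels' protocols, nuclei were digested in situ with AluI, ends were joined with a biotinylated bridge linker, and chromatin was sonicated and immunoprecipitated with RNAPII antibody 8WG16 before tagmentation, biotin selection and PCR. Per the submitters' processing notes, the reads were processed with Trim Galore 0.4.0, BWA and MACS2 2.1.0.20151222 on build hg19. The role of each tool was not given in the sources used here. Per the file headers, loops were called with ChiaSig 1.19.45 from PET clusters within chromosomes, with at least 3 PETs per loop and a span of at least 8000 bp. The lists are marked as pooled, and what was pooled was not given in the sources used here.

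The deposited loop lists give for each loop the count of PETs that join its anchors, which is a whole number and not normalized. They also give the authors' p-value per loop, which was not used beyond the authors' own selection. The highest p-value listed was 0.00207 in CM and 0.000848 in iPSC. A further deposited column followed the distance between anchors and was not used. The deposited H3K27ac list gives for each peak the authors' fold enrichment, which was used to rank peaks. It also gives −log10 values of p and q, of which the deposited q was used in a stricter selection, and a whole-number score that the authors' caller made from the q value and that was not used. Whether the input served as the control of the peak calls was not given in the sources used here. Because the lists hold only loops that passed the caller with 3 or more PETs, a region with no loop is described as having none listed, and no fold is given against it.

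Chromosomes 1 to 22 and X were analysed, which kept 413718 of 414222 CM loops and 369484 of 369821 iPSC loops. Listed PETs were 1600689 in CM and 1578418 in iPSC, and these totals set the scale of every ratio. They are the PETs of called loops, not the sequencing depth of the libraries, which is unknown. A CM loop was shared when both anchors overlapped the anchors of 1 iPSC loop by at least 1 bp, and the share was set against iPSC loops moved within their chromosomes in 20 draws. Anchors were scored for an overlap of at least 1 bp with a CM H3K27ac peak, and shares were set against 100 circular shifts of the peaks within chromosomes. Shares carry 95% exact Clopper-Pearson intervals and ratios of counts carry 95% exact conditional binomial intervals. PETs from PCR without molecular identifiers are not independent molecules, and PETs of 1 loop are not independent of each other, so these intervals cover counting error only. Anchors of different loops can also overlap each other and the same peak, so the intervals of shares are too narrow as well. With 1 list per group no test between the conditions was made, and ratios compare these 2 libraries.

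Each loop added its PETs once to each 25 kb bin that either of its anchors overlapped, and each H3K27ac peak was given to the bin of its midpoint. A bin counted as higher in a library when the ratio of shares of PETs was at least 2, its interval left out 1 and the 2 libraries together held at least 10 PETs. Because PETs arrive in loops, the counts of bins were set against 20 random assignments of whole loops to the libraries. The rule was tried on simulated data with independent PETs over 105272 bins. The changed bins were drawn only from those with at least 50 PETs in the 2 libraries together. Of these, the rule found 20 of 50 changed 2-fold and 50 of 50 changed 4-fold. It called 2.19% of the unchanged bins. Recovery in bins with fewer than 50 PETs was not simulated. The random assignment of loops is the stricter reference.

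The gene tables used here place genes on assembly GRCh38, not on hg19, so no gene was placed on the loops. The comparisons fixed before the data were examined that need promoters (loops between 2 promoters, promoter PETs per gene, TTN, and 17 gene lists of 240 genes, 239 of which had a symbol in the table) were therefore not analysed here. The rule for named items, also fixed before the data were examined, gave in that case the 10 bins of 25 kb with the largest and the 10 with the smallest log2 ratio, after adding 3 PETs, among bins with at least 50 PETs in the higher library. The limit of 50 PETs for the bin counts, the both-anchor measure, the 1 Mb windows and the stitching of H3K27ac peaks up to 12.5 kb apart into domains were chosen after the data were seen. Alternatives changed the PET minimum, the span, the overlap, the peaks, the anchor width, the total of listed CM PETs and the scaling. A relation of loop numbers across chromosomes was also computed and is not reported here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.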

Results

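RNA polymerase II (RNAPII) loops were mapped by in-situ ChIA-PET, in which crosslinked nuclei are digested, nearby DNA ends are ligated through a biotinylated linker, and the ligated fragments are then enriched with an antibody. The 2 ChIA-PET libraries came from human cardiomyocytes (CM) at day 35 of differentiation and from human induced pluripotent stem cells (iPSC) at passage 45. A ChIP-seq list held the H3K27ac peaks, a mark of active promoters and enhancers, of CM at day 35. Each of these groups held 1 list, so the values below have no replicate check, and intervals cover counting error only. All coordinates are those of build hg19.

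The CM list held 413718 loops with 1600689 paired-end tags (PETs) on chromosomes 1 to 22 and X, and the iPSC list held 369484 loops with 1578418 PETs. Both lists had a median of 3 PETs per loop, and the mean was 3.87 in CM and 4.27 in iPSC. The median span between anchors was 75.3 kb in CM (interquartile range 18.0 to 424.6) and 73.3 kb in iPSC (19.2 to 509.1). Loops longer than 10 Mb formed 6.75% of the CM loops (95% exact binomial interval 6.68 to 6.83) and 10.92% of the iPSC loops (10.82 to 11.02). CM loops spanning 100 kb to 1 Mb formed 29.1% of their list, against 25.1% of the iPSC list. The loop with the most PETs in CM, 4056, joined chromosome 11 positions 65163573 to 65198729 and 65250241 to 65280448. In iPSC the first such loop held 1722 PETs and joined chromosome 5 positions 176862644 to 176911085 and 176875613 to 176939727.

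The first comparison asked how many loops the CM and iPSC lists had in common. Of the CM loops, 18386 (4.44%, 4.38 to 4.51) had both anchors over the anchors of 1 iPSC loop, and from the iPSC side 17169 loops (4.65%, 4.58 to 4.72) were shared. The CM share depended on the settings: it was 12.1% with anchors up to 2500 bp apart (15.2% from the iPSC side), 8.81% among loops of at least 5 PETs and 2.27% among spans of at least 20 kb. Shared loops carried 10.2% of the CM PETs and 14.1% of the iPSC PETs. When the iPSC loops were moved by 1 to 5 Mb, a mean of 0.479% of the CM loops were shared (range 0.426 to 0.561 over 20 draws). This level was computed only for all CM loops with the overlap of 1 bp. Shares under other settings, PET classes, span classes or anchor widths have no such reference, and wider anchors or gaps also match more often by chance. Sharing was higher in loops with more PETs: 2.63% of the CM loops with 3 PETs were shared, 50.7% (49.2 to 52.1) of those with 10 to 49 PETs, and 67.0% (62.4 to 71.3) of those with 50 or more. The matching iPSC shares were 2.51%, 38.1% (37.0 to 39.2) and 82.4% (79.6 to 85.0). Anchors were also wider in these classes, with a median of 517 bp in CM loops of 3 PETs and 5753 bp in those of 50 or more. With every anchor set to 2000 bp around its midpoint, 5.6% of the CM loops with 3 PETs, 49.6% of those with 10 to 49 and 49.7% of those with 50 or more were shared, so the 2 highest CM classes had nearly equal shares. The matching iPSC shares were 6.61%, 40.6% and 62.5%.

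**Figure D1:**
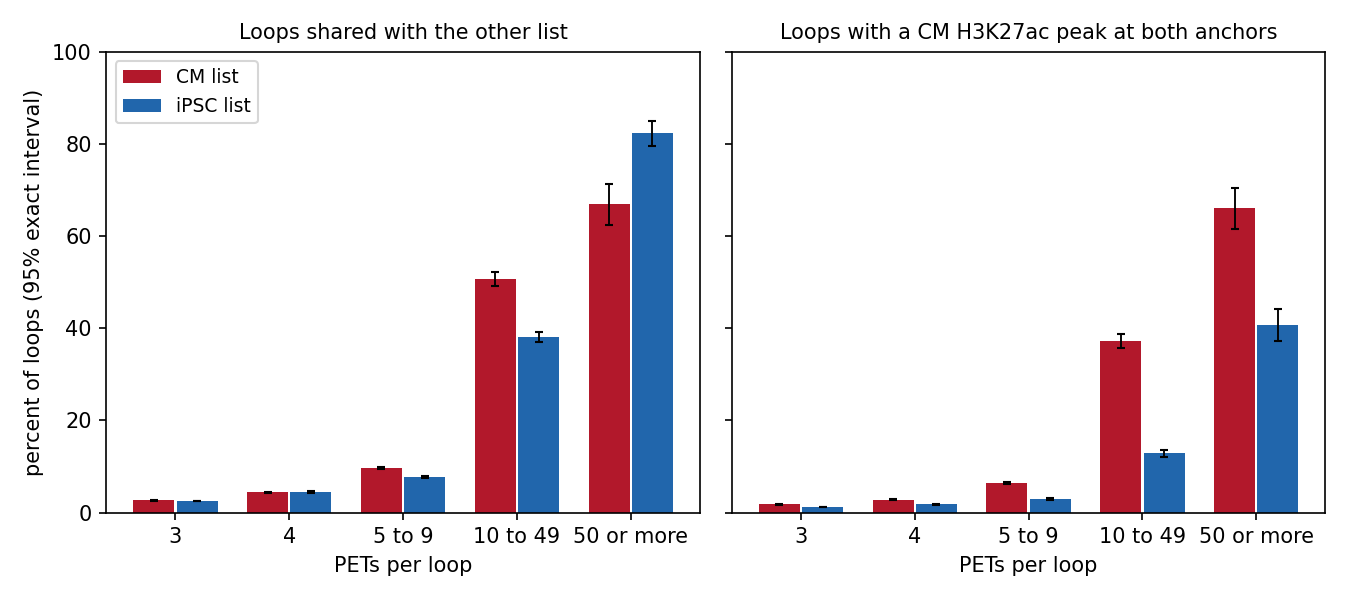
Percent of loops (y axis, from 0) by PETs per loop (x axis) in the CM list (red) and the iPSC list (blue), shared with the other list (left) or with a CM H3K27ac peak at both anchors (right); error bars are 95% exact binomial intervals. In the class of 50 or more PETs, 67.0% of CM and 82.4% of iPSC loops were shared, while 66.1% of CM and 40.8% of iPSC loops had H3K27ac at both anchors.

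The second comparison set the loops against the CM H3K27ac peaks. Anchors of shared loops held a CM H3K27ac peak in 46.0% of cases (45.5 to 46.5), anchors of CM-only loops in 10.4% (10.3 to 10.4) and anchors of iPSC-only loops in 10.5% (10.4 to 10.6). Circular shifts of the peaks within chromosomes gave means of 2.63%, 1.78% and 1.9%, and the observed shares were 17.5, 5.83 and 5.51 times these means. The CM-only share over the iPSC-only share was 0.988 (0.978 to 0.998). Only anchors with identical coordinates were merged, so overlapping anchors on the same peak each counted. These intervals are therefore too narrow, and that of the ratio leaving out 1 does not establish a difference. Among loops of at least 5 PETs this ratio was 1.28, with a peak at 19.5% of CM-only and 15.3% of iPSC-only anchors.

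Loops with H3K27ac at both anchors, a measure added after the data were seen, were more frequent among CM-only loops. They formed 2.38% (2.34 to 2.43) of CM-only loops and 1.22% (1.18 to 1.26) of iPSC-only loops, a ratio of 1.95 (1.88 to 2.02), and the CM-only share was above the iPSC-only share in 23 of 23 chromosomes. The chromosomes came from the same 2 libraries and 1 peak list, so they are not replicates. Loops with H3K27ac at 1 anchor went the other way, with 16.0% (15.9 to 16.1) of CM-only and 18.6% (18.5 to 18.7) of iPSC-only loops. Neither anchor held a peak in 81.6% of CM-only and 80.2% of iPSC-only loops. The order of the both-anchor shares depended on span, here over all loops, shared or not. At 100 kb to 1 Mb they were 2.51% in CM and 1.52% in iPSC. At 1 to 10 Mb they were 0.2432% (0.1975 to 0.2964) in CM and 0.4215% (0.3551 to 0.4966) in iPSC, the reverse order. Among loops with at least 10 PETs, both anchors held H3K27ac in 39.9% of CM-only loops (37.9 to 41.9) and 6.17% of iPSC-only loops (5.51 to 6.89). The shared loops of that size had such anchors in 39.7% of cases in CM and 28.2% in iPSC. Loops of at least 50 PETs that were CM-only had H3K27ac at both anchors in 103 of 147 cases, against 16 of 140 iPSC-only loops. With anchors of 2000 bp, the share with H3K27ac at both anchors among all loops of at least 50 PETs went from 66.1% to 47.6% in CM and from 40.8% to 16.1% in iPSC. H3K27ac was measured in CM alone, so iPSC anchors are described only by their state in CM.

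From the side of the peaks, 68.3% (67.8 to 68.8) of the 37978 CM H3K27ac peaks lay in an anchor of a CM loop and 53.8% (53.3 to 54.3) in an anchor of an iPSC loop. Shifted peaks gave 27.3% and 22.8%. CM anchors without iPSC anchors held 24.2% of the peaks, iPSC anchors without CM anchors 9.65%, and 22.1% of the peaks lay in no anchor of either list. Among the peaks of the highest fold class, 88.2% lay in a CM anchor and 75.9% in an iPSC anchor.

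The third comparison ranked regions by their loop PETs in CM against iPSC, in bins of 25 kb. Of 14809 bins with at least 50 PETs in the higher library, 3149 were at least 2-fold higher in the CM library and 4768 at least 2-fold higher in the iPSC library. Dealing whole loops out to the libraries at random gave means of 1212 and 956 such bins. The median log2 ratio over these bins was -0.39. For the H3K27ac shares by fold, the same bins were classed by the ratio after adding 3 PETs to each count, which places fewer bins past 2-fold than the rule above. CM H3K27ac peaks lay in 79.7% (75.1 to 83.7) of the 359 bins at least 8-fold higher in CM, but in 61.5% (59.6 to 63.4) of the 2625 bins 2- to 8-fold higher in CM, close to the 62.9% (61.7 to 64.0) of those within 2-fold. Taken as a whole, 63.3% of the CM-higher bins held a peak, against 63.5% of the bins higher in neither library. Peaks lay in 52.5% (50.9 to 54.0) of the bins 2- to 8-fold higher in iPSC and in 35.7% (31.0 to 40.6) of those at least 8-fold higher in iPSC. These classes were not matched on PETs: the median of both libraries together was 247, 92, 121, 144 and 355 PETs per bin, from the highest CM class to the highest iPSC class. The balance of the 2 directions depended on the scaling. One other scale was the median ratio over shared loops matched 1-to-1, with at least 20 PETs in the 2 lists together. With it, 6247 bins were higher in CM and 1479 in iPSC, and the median log2 ratio was 0.69. Over all 105272 bins with at least 10 PETs, 26675 were higher in CM and 11480 in iPSC, where random dealing gave 12812 and 12472.

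**Figure D2:**
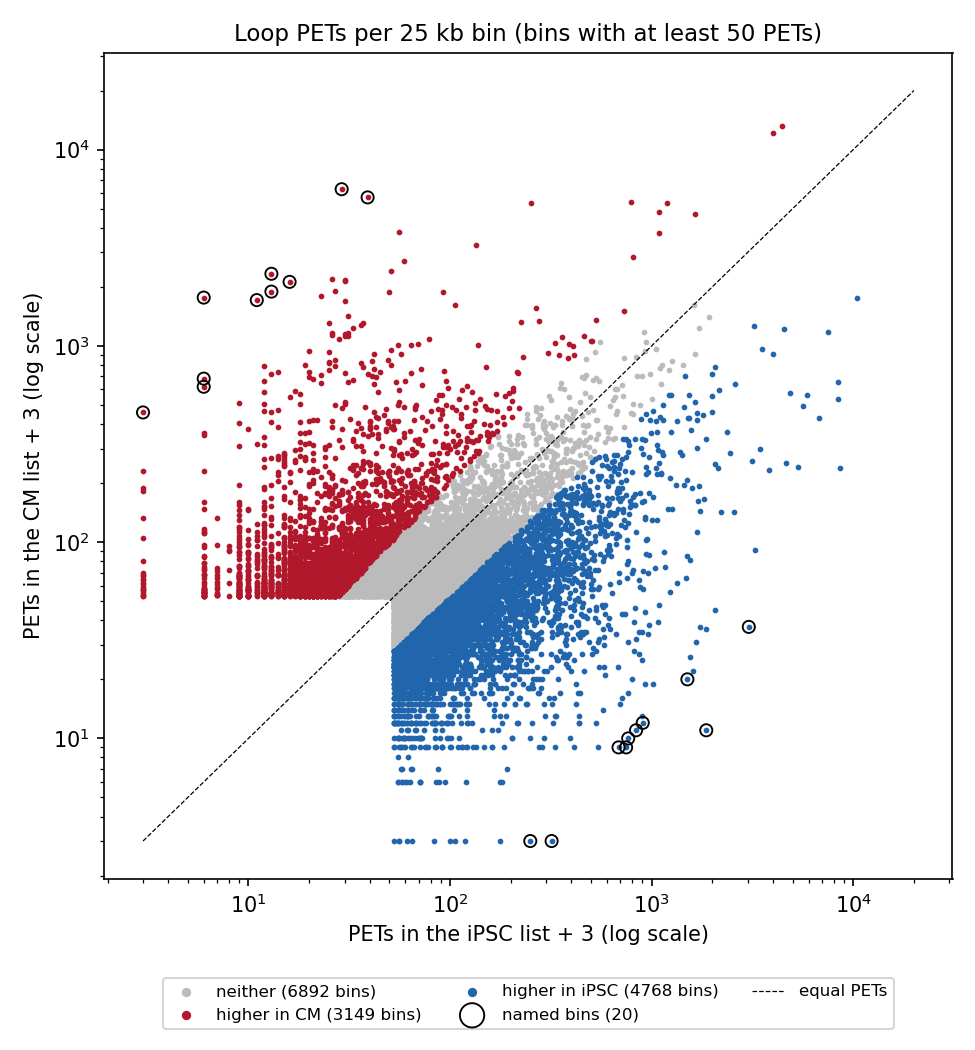
PETs per 25 kb bin in the CM list (y axis) against the iPSC list (x axis), each with 3 PETs added and on a log scale, for bins with at least 50 PETs in the higher library; colours mark bins higher in CM (red, 3149), higher in iPSC (blue, 4768) or neither (grey), circles mark the 20 named bins, and the dashed line marks equal PETs. The named CM bins hold 455 to 6281 CM PETs and at most 36 iPSC PETs.

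The 10 bins with the highest CM ratio lay on 7 chromosomes. First was chromosome 2 from 179650001 to 179675000, with 1759 PETs in CM and 3 in iPSC, a ratio of 578 (198 to 2810). The 3 iPSC PETs were 1 loop at the caller's minimum, and loops below that minimum are not listed. The ratio and its interval therefore describe listed PETs only. Each of the other CM bins had at most 9 iPSC loops, so their ratios share this limit. Neighbouring bins on chromosome 14, 23875001 to 23900000 and 23900001 to 23925000, held 6281 and 5705 CM PETs against 26 and 36 iPSC PETs, ratios of 238 (162 to 365) and 156 (113 to 223). Part of their PETs came from the same loops, among them one of 1902 PETs joining 23876790 to 23902242 with 23902489 to 23920396. The bin on chromosome 1 from 201375001 to 201400000 held 2327 CM and 10 iPSC PETs (ratio 229, 125 to 479). On chromosome 10, the bins starting at 88425001 and 92675001 held 1708 and 2116 CM PETs against 8 and 13 in iPSC. The chromosome 6 bin from 118875001 to 118900000 held 1887 CM and 10 iPSC PETs, including a loop of 303 PETs that spanned 274 kb to 118598194 to 118609002. Chromosome 18 contributed the bin from 2850001 to 2875000, with 455 CM PETs and none listed in iPSC, and the bin from 19750001 to 19775000, with 678 CM and 3 iPSC PETs. Those 3 iPSC PETs were again 1 loop. In the chromosome 18 bin at 19750001, the leading loops reached 346 kb to the left and 389 kb to the right, and both had H3K27ac at each anchor. The chromosome 4 bin from 95300001 to 95325000 drew 548 of its 616 CM PETs from 1 loop of 45.6 kb.

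All 10 of these CM bins held CM H3K27ac peaks. The peak of highest fold, 40.6, lay in the chromosome 14 bin at 23900001, and the highest in the chromosome 6 bin had a fold of 4.33. Over all bins at least 8-fold higher in CM that held a peak, the median of the highest fold was 13.9. The chromosome 10 bin at 88425001 held 11 peaks with a highest fold of 36.6, and 163 of its 168 loops in CM had H3K27ac at 1 anchor or both. With loops counted instead of PETs, also after adding 3, the log2 ratio went from 8.18 to 5.40 in the chromosome 2 bin, from 7.74 to 3.02 and from 7.17 to 2.59 in the chromosome 14 bins at 23875001 and 23900001, and from 6.67 to 1.54 in the chromosome 4 bin.

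The 10 bins with the highest iPSC ratio lay on 6 chromosomes, and 8 of them held no CM H3K27ac peak. The chromosome 3 bin from 46600001 to 46625000 was first, with 1863 iPSC and 8 CM PETs, a ratio of 236 (120 to 548). The 8 CM PETs came from 2 loops, so these ratios also describe listed PETs only. The bin held 6 CM H3K27ac peaks, the highest with a fold of 8.12. The chromosome 4 bin from 113550001 to 113575000 held 3030 iPSC and 34 CM PETs (ratio 90.4, 64.5 to 131), with a loop of 1246 PETs over 109 kb. The chromosome 13 bin from 56150001 to 56175000 and the chromosome 3 bin from 176025001 to 176050000 held 316 and 247 iPSC PETs, with none listed in CM. Chromosome 3 also held the bins at 54650001 (900 iPSC and 9 CM PETs) and 109025001 (1501 and 17). The bins at 223175001 on chromosome 1, 24425001 on chromosome 7, 147200001 on chromosome 5 and 51750001 on chromosome 13 held 744, 762, 682 and 834 iPSC PETs, against 6, 7, 6 and 8 in CM. The log2 ratio of the chromosome 5 bin at 147200001 went from -6.27 to -2.50 when only spans of at least 20 kb were kept.

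Around the first CM bin, the chromosome 2 bins from 179400001 to 179800000 formed an unbroken run of 400 kb in which every bin was higher in CM. Between 179350001 and 179850000 the CM list held 355 loops with 2865 PETs and the iPSC list 11 loops with 38 PETs. Of the 186 CM loops with an anchor in the bin from 179650001 to 179675000, 172 stayed inside this region. Each loop added its PETs to every bin that its anchors touched. The bins of the run therefore share loops and are not separate observations. That bin also held the strongest of the region's 19 H3K27ac peaks, from 179667872 to 179674075, with a fold of 32.6, which was at percentile 99.3 of the list. The loop with the most PETs at the bin, 169, joined 179633041 to 179645804 with 179649037 to 179661163, and neither anchor held a CM H3K27ac peak. The next, with 149 PETs, joined 179668369 to 179674391 with 179678528 to 179687224, and both anchors held a peak. Other peaks of high fold in the region lay at 179493564 to 179494952 (fold 16.4) and 179727715 to 179730697 (fold 17.0).

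**Figure D3:**
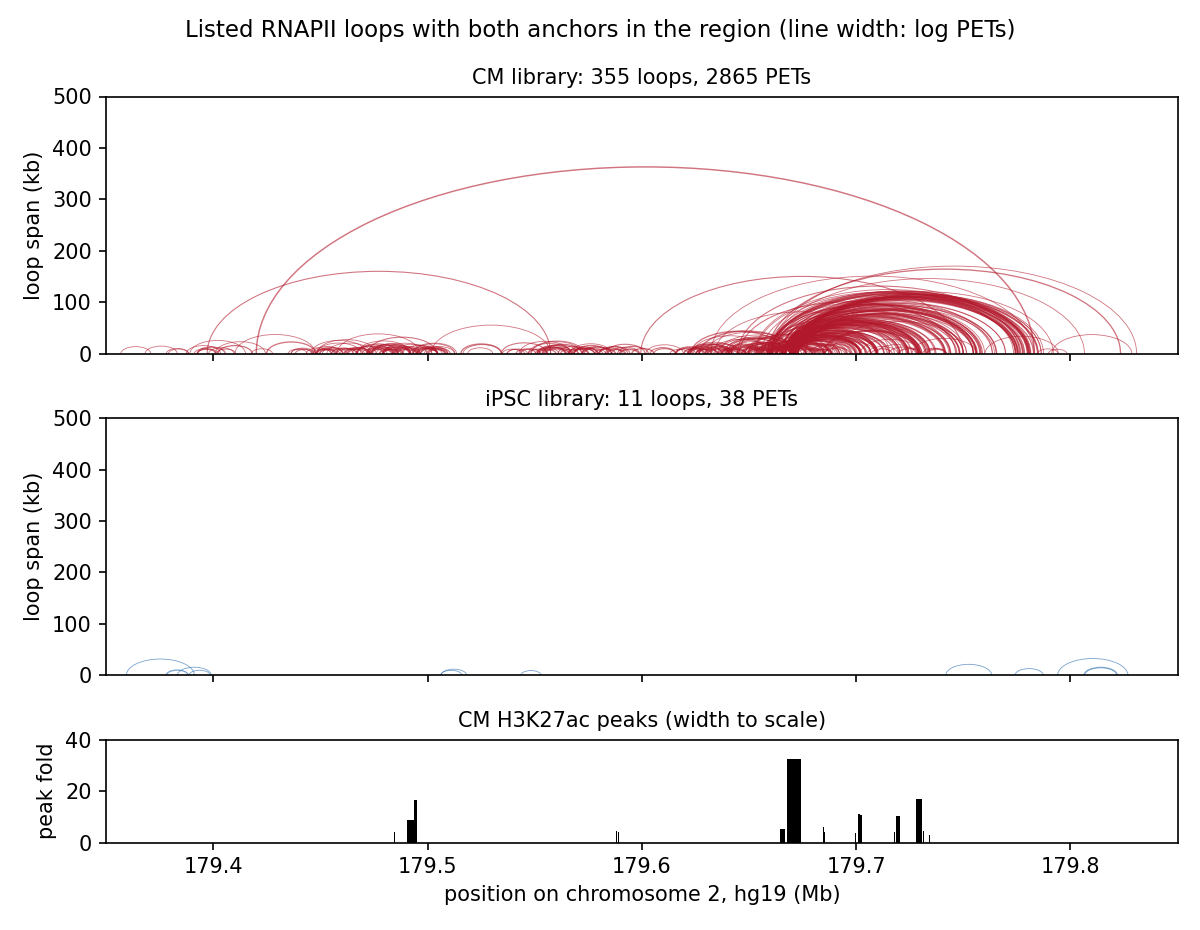
Listed loops with both anchors between 179350001 and 179850000 on chromosome 2 (hg19; x axis, position in Mb) in the CM list (top, 355 loops) and the iPSC list (middle, 11 loops), with arc height showing loop span in kb and line width the log of the PETs; the bottom panel shows the fold of the 19 CM H3K27ac peaks at their true widths. The widest peak, at 179667872 to 179674075, lies in the bin that holds an anchor of 172 of the CM loops drawn.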

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

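The iPSC list held 3 loops on the mitochondrial genome with 2817 PETs together, a signal outside the chromosomes compared. The highest of them, with 2173 PETs, was the loop with the most PETs in the iPSC file, and the 3 loops made up 0.178% of that file's PETs. No mitochondrial loop was listed in CM. Differences between samples of 1 group were not examined, since each group held 1 sample.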

How the results depend on the processing

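All alternatives for bins, both-anchor shares, PET classes and long loops were chosen after the data were seen. No paired analysis was possible because each group held 1 sample and no test was made. The share of CM loops shared with iPSC was 4.44% and became 8.81% for loops of at least 5 PETs, 2.27% for spans of at least 20 kb, 12.1% with anchors up to 2500 bp apart and 3.12% with the overlap at no less than 0.5 of the shorter anchor. Thinning the CM PETs to the iPSC total gave 4.50%. The listed totals were nearly equal (1600689 and 1578418), so thinning could change little and does not address sequencing depth. The cause of these shifts was not tested, and no moved-loop share was computed for these alternatives. The ratio of H3K27ac at CM-only over iPSC-only anchors, 0.988, changed direction for loops of at least 5 PETs (1.28) and spans of at least 20 kb (1.03), and was 1.0 for the upper fold class of peaks. It was 0.884 when 0.5 of the peak had to lie in the anchor and 0.937 with anchors of 2000 bp; the cause was not tested. The ratio for both anchors, 1.95, stayed above 1 in each of these settings: 2.72 (at least 5 PETs), 2.09 (upper fold class), 1.88 (0.5 of the peak) and 1.58 (2000 bp). None of these settings took long loops alone. Over all loops of 1 to 10 Mb the both-anchor share was lower in CM (0.2432%) than in iPSC (0.4215%). The CM-higher bins numbered 1145 with loops of at least 5 PETs, 1910 with spans of at least 20 kb, 1803 with loops counted instead of PETs, 6247 with the scale of shared loops of at least 20 PETs and 26675 with no minimum of 50 PETs. The iPSC-higher bins numbered 2124 with loops of at least 5 PETs, 3665 with spans of at least 20 kb, 4046 with loops counted, 1479 with the scale of shared loops of at least 20 PETs and 11480 with no minimum. The limits of 5 PETs and 20 kb leave fewer loops, and the scale moved every log2 ratio alike; the other causes were not tested. Both scales from shared loops used only 1-to-1 matches, and the limit of 20 counted the PETs of both lists together. The median ratio of the 11397 matches was 1.0, a log2 of -0.02 from the scale of all PETs. Both lists had a median of 3 PETs per loop, the caller's minimum, which draws this median towards 1. It is therefore no check of the scale of all PETs. The median ratio of the 1392 matches with at least 20 PETs was 0.479, a log2 of -1.08 from that scale. All 20 named bins kept their direction and the rule of 2-fold in 100 of 100 values over 5 settings, with much smaller log2 ratios when loops were counted (1.54 for chromosome 4 95300001). These bins were picked from the same data for their extreme ratios. The settings of scale shift every log2 ratio alike, and the others reuse the same loops. Keeping the rule was therefore nearly assured and is no independent check. The alternatives planned for promoters, gene lists and TTN, and anchors away from promoters, were not run, since no gene was placed.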

Other observations

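The stitching of peaks and every test below except that of chance ligation were chosen after the result was seen. CM H3K27ac peaks stitched over gaps of up to 12.5 kb gave 17996 domains. Of the 100 with the most signal, 72 had at least 2-fold more loop PETs in CM and 7 in iPSC, with a median log2 ratio of 2.14. Of the 983 tested among the first 1000, 49.9% (46.8 to 53.1) were higher in CM and 12.2% (10.2 to 14.4) in iPSC, against 25.9% and 24.5% of the 9788 tested among the remaining 16996. Domains with fewer than 10 PETs in the 2 libraries together were not tested. The domains were counted only under the scale of all listed PETs. The balance of the bins depended on the scale, and that of the domains was not computed under another one. The classes of domains were not matched on PETs or width, and no random dealing of loops was made for them. The first domain, chromosome 1 from 201660955 to 201743382, held 1435 CM and 98 iPSC PETs. The domains on chromosome 20 from 42742361 to 42818249 and on chromosome 8 from 11531768 to 11584092 held 2280 and 3028 CM PETs against 64 and 58 in iPSC. An exception was chromosome 19 from 39137734 to 39214067, with 500 CM and 464 iPSC PETs.

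Over windows of 1 Mb, the largest excess of iPSC PETs, as a difference after scaling, lay on chromosome 6. The window from 26 to 27 Mb held 26364 iPSC and 3871 CM PETs, 6.91-fold more (6.68 to 7.15), and the window from 27 to 28 Mb held 18724 and 1762 PETs, 10.8-fold more (10.3 to 11.3). In each window 25 bins were higher in iPSC and 0 were higher in CM. These values compare listed PETs under the scale of all listed PETs. The scale of shared loops of at least 20 PETs differs by a log2 of -1.08 and would lower the iPSC folds. The window with the largest excess of CM PETs was chromosome 11 from 65 to 66 Mb, with 15943 CM and 7796 iPSC PETs, although 9 of its bins were higher in CM and 10 in iPSC. The bin of that window at 65250001 held the most PETs of the CM list, 13240, and 4417 iPSC PETs.

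Loops longer than 10 Mb were 1.62 times as frequent in the iPSC list as in the CM list, and 2.07 times among loops of at least 5 PETs (12.2% against 5.87%). Very few of these long loops were shared between the lists: 22 of 27944 in CM (0.0787%) and 24 of 40334 in iPSC (0.0595%). Among spans of 8 to 20 kb, 10.1% of the CM and 10.9% of the iPSC loops were shared. No moved-loop share was computed by span, so the chance level of either span class is not known. Both anchors held a CM H3K27ac peak in 0.233% of the long CM loops and 0.273% of the long iPSC loops. The excess was 1.58 (1.56 to 1.61) without the 792 bins that held at least 5 such loops in either list, which argues against a few multi-copy or very active bins as the whole cause. Chance ligation between anchors that carry many PETs stays open. The ratio was 1.86 (1.8 to 1.93) among loops whose anchors both lay in bins below their list's median of short-range PETs, but that selection removes short loops and by itself raised the share of long loops, to 11.2% in CM and 20.9% in iPSC, so it decides nothing. The pooling and the cell type stay open as well, untested.

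Over all tested bins, CM H3K27ac peaks lay in 26.7% of iPSC-higher bins and 18.1% of CM-higher bins. A candidate explanation is that the iPSC-higher bins carry more PETs. With the CM-higher bins weighted to the same PETs of both libraries together, the shares were 26.3% and 37.9%, a ratio of 0.695, and the CM-higher share was above in 14 of 15 PET classes. That order is consistent with PETs per bin as the source of the first one. Whether the matched difference is biological was not tested further. Before matching, bins higher in neither library held a peak in 16.9% of cases, close to the CM-higher bins. The iPSC-higher bins numbered 11480, fewer than the mean of 12472 from random dealing of whole loops.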
